A study of Mus musculus with 6 samples.

How the data were processed

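Poly(A) RNA-seq libraries of RAW 264.7 cells were compared between 2 groups of 3 libraries, scramble guide and Cited1 knockout clone 9. Groups and replicate numbers were taken from the titles in the labels. Per the labels' protocols, cells were transduced with lentivirus encoding Cas9 and a guide, selected, and diluted to clonal lines, and libraries were made with a kit that keeps strand information and with poly(A) selection. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.3a, featureCounts, edgeR and Cuffdiff 2.2.1 without saying what each was used for. The genome build and annotation the authors aligned to are not given in the sources used here.

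The deposited gene files hold raw read counts in the layout of STAR's gene count output, with 3 count columns per gene (unstranded, forward strand and reverse strand) and 4 summary lines for reads not assigned to a gene. These lines were left out of library sizes and tests; they held 3.29% to 4.86% unmapped and 4.58% to 5.75% multiply mapped reads. Reads that map to several places are not in the gene counts, so genes with near-identical copies are undercounted. The authors' deposited table gives for each transcript a linear fold change with its direction, a total FPKM over both groups and a q-value; its highest q-value is 0.0498, and the filter and test behind it are not stated in it. It was used only for the comparison with that table.

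The reverse-strand column was fixed for the tests before the data were examined, because the kit named in the labels marks strand. In these libraries the reverse column held 49.6% to 49.7% of the reads of both strand columns, so the counts show no strand preference. Gene by gene, the reverse share had a median of 49.7% (5th to 95th percentile 46.6% to 53.3%) over 13054 tested genes with at least 100 reads in both columns together, and lay between 40% and 60% in 99.3% of them. The choice was kept and the unstranded column was run as an alternative. Without strand, reads of a gene and of a gene overlapping it on the other strand cannot be told apart, so overlapping and antisense genes are uncertain. Depth on the reverse column was 10490791, 11982154 and 12655065 counts in scramble replicates 1, 2 and 3, and 10862975, 13873733 and 10508165 in the knockout replicates. The 10 most abundant genes held 4.80% to 6.11% of the counts. At this depth a gene at 1 CPM has about 10 counts in a library.

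Gene symbols came from GENCODE M21, which named 94.0% of the 55414 gene IDs in the files; IDs without a symbol held 0.380% of the counts. Where several IDs share a symbol, the one with the most counts kept it; 1 tested ID was affected. Positions are those of the same annotation on GRCm38. The guide was matched to its transcripts exactly, on both strands.

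Genes were kept with edgeR's filterByExpr, counts were scaled by TMM factors (0.928 to 0.947 in scramble, 1.06 to 1.07 in the knockout), and groups were compared with edgeR 4.0.16 (robust glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The biological coefficient of variation was 0.0735. CPM values use the TMM-scaled library sizes; the SE of a log2 fold change is from log2 CPM per library with a prior count of 2. A fold against a group at 0 counts is a lower bound at 3 counts over the group; with 1 to 3 counts a ratio with its exact 95% interval is given. Gene lists and chromosomes were tested with camera in limma 3.58.1 on the same fit (inter-gene correlation 0.01, adjustment over the 29 lists with at least 3 tested members, and over 20 chromosomes). The 32 lists hold 734 distinct genes, of which 592 were tested; they were written from general knowledge of macrophages before the data were examined. Python 3.11.15 and matplotlib 3.10.9 drew the figures.

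Genes named in the text follow a rule fixed before the data were examined. They are Cited1, the 12 largest increases and 12 largest decreases among genes past the threshold with at least 2-fold change, at least 10 CPM in the higher group, libraries that do not overlap and a symbol that is not a predicted model, and in each list up to 2 risen and 2 fallen members with the smallest adjusted p. Some genes of the last part are left out of the text, also in lists where other members are named. Values of genes outside the rule are given only in the closing section.

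Replicates of a group differed from each other by more than counting noise (chi-square per degree of freedom 2.84 to 7.21 over genes), so each counted as 1 sample. The test was checked on simulated counts for 12936 genes, with 200 changed singly and a further 30 shifted together as a list by 0.5 in log2: it recovered 73.1% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold, and 13 of its 200 calls (6.5%) were false. In the same simulation camera called the shifted list and did not call an unshifted one. The simulated genes were drawn independently of each other, and far fewer changed than the 69.1% called in these data. The check therefore does not cover lists of correlated genes or a change as broad as the one seen here. Alternatives were RLE factors, library size only, no filter or at least 1 CPM in 3 libraries, unstranded counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, an estimated inter-gene correlation and fry. Corrections for GC content and transcript length, and a restriction to genes without a gene on the other strand, were added after seeing the data.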

Results

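RNA from RAW 264.7 cells, a mouse cell line that resembles macrophages and is widely used to study inflammatory responses, was sequenced after poly(A) selection. The cells had been transduced with a lentivirus carrying Cas9, the nuclease of CRISPR editing, together with a guide RNA. The 3 scramble libraries came from cells with a guide that targets no gene, and the 3 knockout libraries came from cells of clone 9, made with a guide against Cited1. CITED1 is a transcriptional coregulator that has no DNA-binding domain of its own and acts through partners such as CBP and p300. The comparison asks how loss of CITED1 changes macrophage gene expression, and the series is about genes stimulated by interferon-γ (IFNγ), a cytokine that activates macrophages through STAT1. The labels used here do not say whether IFNγ or another stimulus was given to these 6 libraries. Their shared extraction protocol mentions a microbe, without saying whether these cells were exposed to it. Differences between the groups may therefore be those of resting cells or of a response to a stimulus. Each library held 24102697 to 32290914 reads, of which 10490791 to 13873733 were counted in genes on the strand column used for the tests. All values below are counts scaled to library size (CPM) given as mean ± SD with n = 3 libraries per group, unless stated otherwise. Because 1 knockout clone was sequenced, effects of the knockout and of the clone could not be separated, and the labels do not say whether the scramble cells were a clone or a pool. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

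The targeted gene was measured first. Cited1 (ENSMUSG00000051159) lies on the minus strand of chromosome X at 102247381 to 102252181 in GRCm38. The guide TACCCCGGGGTCACCGCAAA matched its transcript ENSMUST00000050551.9 at 102247911 to 102247930, in the coding part of exon 3 of 3, and was followed there by the bases TGG, a motif that Cas9 requires. Its first base was coding base 139 of 609, in codon 47 of 203, and no transcript of another gene held the sequence. The scramble guide GTGTAGTTCGACCATTCGTG matched 0 annotated transcripts. Cited1 was counted 53, 40 and 49 times in scramble replicates 1, 2 and 3, and 24, 13 and 14 times in the knockout replicates. Its level was 4.37 ± 0.98 CPM in scramble and 1.40 ± 0.60 CPM in the knockout, a log2 fold change of -1.65 (SE 0.36; edgeR adjusted p = 0.000221). An exact two-sided permutation test gave p = 0.1, the smallest p that 3 libraries against 3 allow. Cited1 transcript was therefore still counted in each knockout library, and these counts do not show whether it encodes protein. In the authors' deposited table Cited1 was also lower in the knockout, by 6.71-fold (q = 0.000364).

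**Figure D1:**
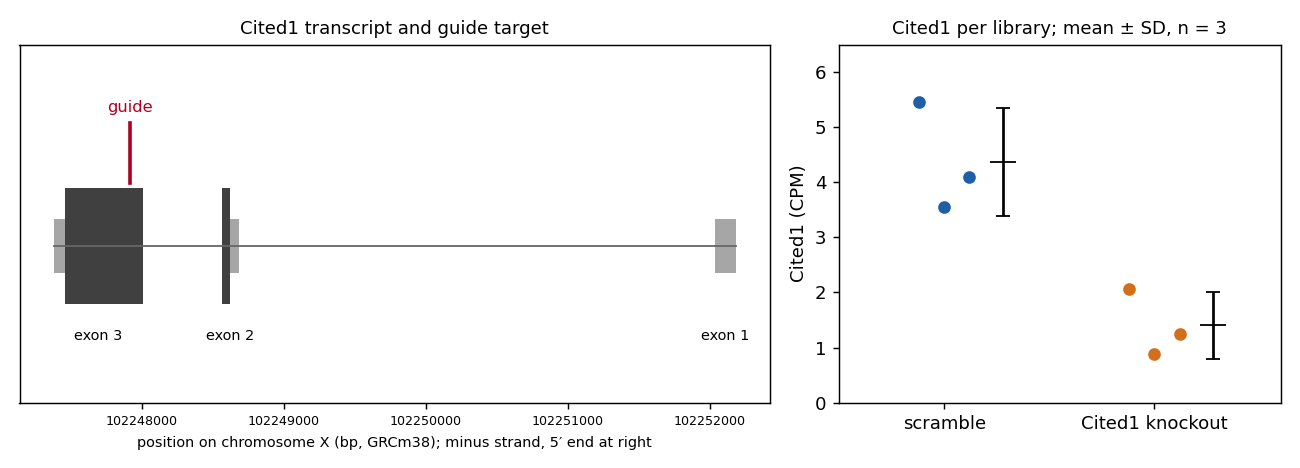
Left, the Cited1 transcript on chromosome X (GRCm38 position in bp), with exons in light grey, coding parts in dark grey and the guide target in red. Right, Cited1 in CPM for each library (points) with mean ± SD for n = 3, 4.37 ± 0.98 in scramble and 1.40 ± 0.60 in the knockout.

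Across the transcriptome, the groups differed in most of the genes tested. Of 13112 genes, 9061 (69.1%) changed at a false discovery rate of 0.05 in edgeR's quasi-likelihood test, with 4529 higher and 4532 lower in the knockout. A change of at least 2-fold was seen in 3361 genes (25.6%), of which 1546 were higher and 1815 lower. The 3 libraries of one group lay entirely above those of the other in 9477 genes (72.3%), where chance gives 10% of genes. Within a group, log2 CPM values correlated across genes at r of 0.986 or more, against at most 0.892 between groups (genes are not independent replicates). With the unstranded counts, 9108 of 12687 genes changed, and 8095 of the calls were shared in the same direction. Scaling by library size alone raised the median log2 fold change of all genes by 0.18 and made 61.4% of the calls higher, against 50.0% with the scaling used here, so each change is relative to that choice.

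The genes with the largest increases included the class II transactivator Ciita (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418), which switches on the genes of major histocompatibility complex (MHC) class II. Ciita went from 7.21 ± 1.36 to 139 ± 20.1 CPM, a log2 fold change of 4.25 (SE 0.19; edgeR adjusted p = 4.06e-15). Its target H2-Aa (chromosome 17, 34282744 to 34287823) rose from 129 ± 23.7 to 2174 ± 154 CPM, and H2-DMb1 from 9.47 ± 1.66 to 148 ± 10.1 CPM. H2-Ea-ps, a class II gene annotated as a polymorphic pseudogene, rose from 62.4 ± 12.9 to 1069 ± 75.4 CPM. Whether these cells carry an intact copy was not tested. Class II genes resemble each other and vary between strains, so reads may be shared or lost among them. Further large increases were seen in Arrdc4 (0.30 ± 0.08 to 26 ± 6.07 CPM), the cyclophilin gene Ppic (0.36 ± 0.07 to 14.2 ± 1.85 CPM), Asb2 (0.26 ± 0.23 to 10.2 ± 2.38 CPM), the membrane protease gene Tmprss4 (0.51 ± 0.24 to 17.9 ± 2.31 CPM) and Fads6 (1.44 ± 0.41 to 28.1 ± 2.14 CPM). Plod2, a collagen lysyl hydroxylase gene, had 3 counts over the scramble libraries and 1003 over the knockout libraries, a ratio of 294 (95% counting interval 100 to 1428). Chchd10 (11.3 ± 1.74 CPM in the knockout) and Mmp11 (11.3 ± 1.18 CPM) also rose, but they overlap each other on opposite strands and neither could be tested in the unstranded counts.

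Among the largest decreases were genes that were almost absent from the knockout. Maged1 (chromosome X, 94535474 to 94542143) fell from 40.9 ± 2.89 CPM to 0 counts, at least 509-fold lower when 3 counts over the group are taken as the floor. By the same floor Adgrl2, an adhesion receptor gene, was at least 189-fold lower, the purinergic receptor gene P2ry14 at least 175-fold and the sodium-proton exchanger gene Slc9a7 at least 149-fold. Rgs16, a regulator of G-protein signalling, had 3648 counts over the scramble libraries and 3 over the knockout libraries, a ratio of 1383 (95% counting interval 473 to 6709). Maf, a transcription factor gene of macrophages, had 1780 and 3 counts, a ratio of 675 (231 to 3275). The secreted glycoprotein gene Stc2 had a ratio of 444 (152 to 2157), and the prolyl hydroxylase gene P4ha2 one of 393 (70.2 to 15586). The anti-inflammatory cytokine gene Il10 fell from 73.3 ± 6.39 to 0.21 ± 0.29 CPM, Emp2 from 65.9 ± 8.38 to 0.16 ± 0.14 CPM, the transcription factor gene Runx3 from 56.3 ± 4.85 to 0.30 ± 0.27 CPM and Marcks from 18.5 ± 2.95 to 0.11 ± 0.13 CPM. Of these 24 genes, 8 overlap a gene on the other strand, among them Plod2, Ciita, P2ry14, Rgs16 and Maf, and their counts can include reads of that gene. Counting intervals and floors cover counting error only.

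**Figure D2:**
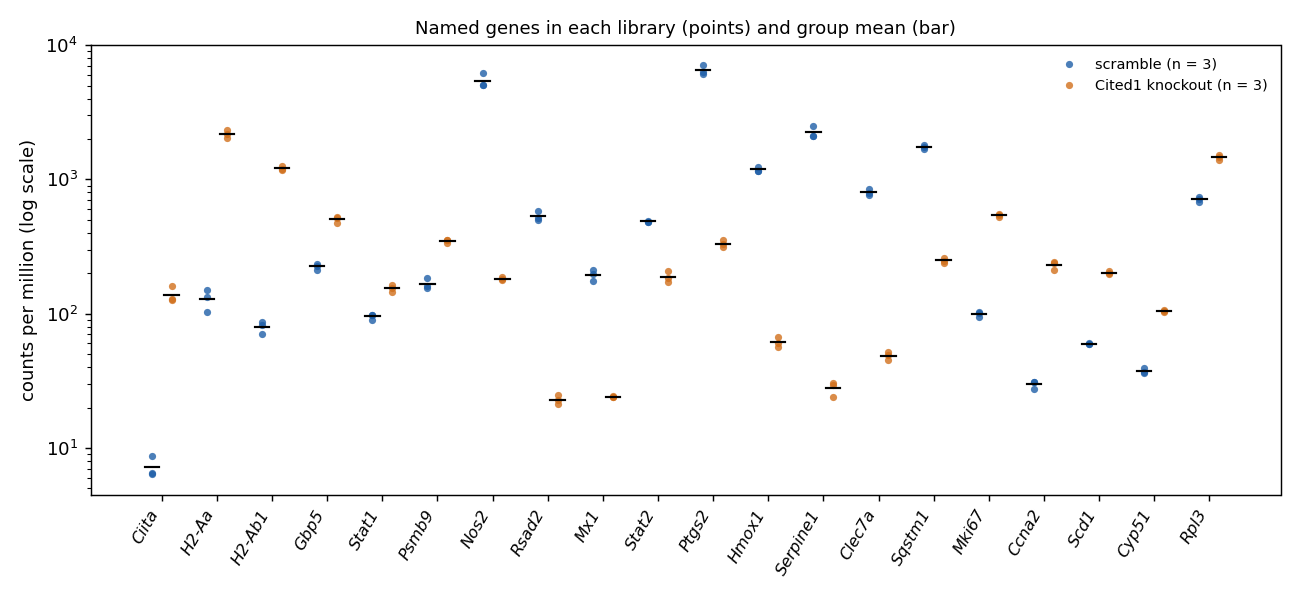
CPM on a log axis for 20 genes named in the text, in each scramble library (blue) and each Cited1 knockout library (orange), with n = 3 per group and black bars at the group means. Ciita, H2-Aa and Mki67 lie higher in all 3 knockout libraries, and Nos2, Rsad2, Ptgs2, Hmox1 and Serpine1 lie lower.

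Gene lists were then compared with the other genes by camera. Of 32 lists, 29 had enough tested members, and 5 were higher and 15 lower in the knockout at an adjusted p below 0.05 with a preset inter-gene correlation. With the correlation estimated from the libraries, 9 of those 20 calls held, 3 higher and 6 lower. A higher correlation cannot account for every loss. Osteoclast differentiation and TGF-β genes had estimates of -0.056 and -0.012, below the preset 0.01, and still lost their calls. What else differs in camera under that setting was not examined, so a lost call does not by itself measure correlation. Counts of members are at a false discovery rate of 0.05 over all genes tested. Adjusted over the list alone, the counts were the same except in 4 lists, where they are given.

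Genes of the type I interferon response, which encode antiviral proteins and are driven by STAT1, STAT2 and IRF9 together, were lower in the knockout. All 39 members tested fell, 30 of them at least 2-fold, and the list median was a log2 fold change of -1.63 (camera adjusted p = 1.32e-32). The call was lost in the setting with an estimated correlation, which was 0.358 for this list (camera adjusted p = 0.0545 with an estimated correlation). Rsad2, which encodes the antiviral protein viperin, fell from 533 ± 42.7 to 22.9 ± 1.7 CPM, and Mx1, an antiviral GTPase gene, from 194 ± 18.2 to 24.1 ± 0.39 CPM. Stat2 itself fell from 486 ± 5.18 to 187 ± 17.8 CPM.

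The IFNγ list did not move one way. Of 34 members tested, 14 rose and 14 fell, the median log2 fold change was 0.00028, and camera gave an adjusted p of 0.483. With library size scaling the median was 0.18 and with RLE factors -0.0074, so it has no stable sign. Besides Ciita, the guanylate-binding protein gene Gbp5 rose from 225 ± 10.7 to 505 ± 25.0 CPM. In the other direction, Nos2, the inducible nitric oxide synthase gene (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), fell from 5416 ± 652 to 182 ± 5.16 CPM, a log2 fold change of -4.90 (SE 0.10; edgeR adjusted p = 3.78e-20). Slfn1 fell from 89.4 ± 3.21 to 5.29 ± 0.96 CPM.

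In the JAK-STAT list, 3 of 26 members rose and 20 fell (median -0.65; camera adjusted p = 0.000446, and adjusted p = 0.0692 with an estimated correlation). Jak2, a kinase of the IFNγ receptor, fell from 455 ± 13.5 to 194 ± 14.1 CPM, while Stat1 rose from 95.3 ± 4.91 to 155 ± 9.45 CPM. The phosphatase gene Ptpn2 rose slightly, from 51.9 ± 2.16 to 61.7 ± 1.66 CPM, a change that did not pass after correction for GC content and transcript length (edgeR adjusted p = 0.0808). The CITED and CBP/p300 list had 4 members tested and all 4 fell. They include the targeted gene Cited1, the only one at least 2-fold lower, whose fall says nothing about its partners. Ep300 fell from 135 ± 11.3 to 86.7 ± 4.38 CPM. The list was not called by camera (adjusted p = 0.224), except in limma-voom (camera adjusted p = 0.0429). The fry test, which does not compare a list with other genes, called it lower (fry adjusted p = 0.00287).

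Antigen presentation by MHC class II rose as a list. Of 15 members, 12 rose, 10 of them at least 2-fold, and 3 fell (median log2 fold change 2.08; camera adjusted p = 1.06e-15, and adjusted p = 0.0263 with an estimated correlation). H2-Ab1 rose from 80.0 ± 8.53 to 1207 ± 47.3 CPM. The protease gene Ctss fell from 1244 ± 20.6 to 931 ± 25.6 CPM, and Rfxap, part of the complex that binds class II promoters, from 23.8 ± 1.93 to 15.2 ± 1.32 CPM. For MHC class I presentation, 11 of 21 members rose and 3 fell, and the list was not called (median 0.19; camera adjusted p = 0.0935), although camera called it higher with library size scaling (adjusted p = 0.0264), without the low-count filter (0.0369) and in limma-voom (0.0357). Psmb9, an immunoproteasome subunit gene, rose from 167 ± 14.5 to 349 ± 10.0 CPM and the peptidase gene Erap1 from 111 ± 3.05 to 195 ± 13.3 CPM. The class I activator Nlrc5 fell from 274 ± 6.33 to 173 ± 16.6 CPM, and H2-D1 from 3197 ± 16.7 to 2385 ± 94.1 CPM.

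Inflammatory cytokine and chemokine genes driven by NF-κB were lower in the knockout. Of 27 members, 4 rose and 20 fell, or 4 and 21 adjusted over the list alone (median -1.14; camera adjusted p = 7.65e-12, and adjusted p = 0.0292 with an estimated correlation). Ptgs2, which encodes the inducible cyclooxygenase (chromosome 1, 150100031 to 150108227), fell from 6519 ± 511 to 331 ± 20.7 CPM, and the chemokine gene Ccl9 from 645 ± 14.1 to 29.9 ± 2.82 CPM. Birc3 rose from 84.8 ± 1.48 to 127 ± 13.1 CPM and Relb from 28.8 ± 1.2 to 44.6 ± 3.86 CPM. Immediate early genes, which respond to stimuli without new protein synthesis, fell in 21 of 25 members and rose in 2, or 22 and 2 adjusted over the list alone (median -1.82; camera adjusted p = 1.18e-21, and adjusted p = 0.0386 with an estimated correlation). Zfp36, whose protein promotes decay of cytokine messages, fell from 861 ± 15.2 to 120 ± 6.26 CPM, and Atf3 from 681 ± 52.5 to 107 ± 6.62 CPM. Klf2 rose from 10.3 ± 2.42 to 34.8 ± 4.33 CPM and Nr4a2 from 1.13 ± 0.71 to 5.03 ± 2.15 CPM. All 7 tested genes of alternative activation fell (median -1.34; camera adjusted p = 1.14e-05, and adjusted p = 0.0386 with an estimated correlation), among them the scavenger receptor gene Msr1 (521 ± 27.8 to 279 ± 17.2 CPM).

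Macrophage identity genes fell in 22 of 27 members and rose in 4 (median -1.93; camera adjusted p = 1.40e-11, and adjusted p = 0.0332 with an estimated correlation). The transcription factor gene Cebpb fell from 380 ± 22 to 56.4 ± 1.33 CPM. Cd68 rose from 266 ± 5.24 to 534 ± 19.8 CPM and the lipid receptor gene Trem2 from 3.57 ± 1.19 to 21.2 ± 3.06 CPM. Pattern recognition receptors fell in 24 of 29 members and rose in 3 (median -1.26; camera adjusted p = 4.85e-10), a call that was lost with an adjusted p = 0.107 with an estimated correlation. The fungal glucan receptor gene Clec7a fell from 799 ± 46.2 to 48.7 ± 3.49 CPM and Clec4e from 526 ± 17.7 to 38.2 ± 1.64 CPM, while Cgas rose from 26.3 ± 1.09 to 57.0 ± 4.02 CPM and Tlr2 from 21.4 ± 2.70 to 46.9 ± 0.97 CPM. In the list of NADPH oxidase and phagocyte killing, 1 of 13 members rose and 10 fell, or 1 and 11 adjusted over the list alone (median -0.57; camera adjusted p = 5.34e-05, and adjusted p = 0.0547 with an estimated correlation). Its oxidase subunit Ncf2 fell from 302 ± 7.58 to 135 ± 5.56 CPM. Lyz1 rose from 0.44 ± 0.32 to 2.10 ± 0.68 CPM, but it closely resembles Lyz2 and its counts are uncertain.

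Lysosome and autophagy genes fell in 22 of 28 members and rose in 3 (median -0.73; camera adjusted p = 3.07e-08, and adjusted p = 0.107 with an estimated correlation). The cathepsin gene Ctsl fell from 812 ± 14.3 to 102 ± 3.78 CPM, and the autophagy receptor gene Sqstm1 from 1742 ± 49.9 to 249 ± 11.3 CPM. Hexa rose from 150 ± 10.9 to 220 ± 11.5 CPM and Gusb from 142 ± 8.39 to 207 ± 20.4 CPM. In the NRF2 list of the oxidative stress response, 13 of 15 members fell and 1 rose (median -0.95; camera adjusted p = 3.22e-10, and adjusted p = 0.0332 with an estimated correlation). The heme oxygenase gene Hmox1 fell from 1186 ± 45.9 to 61.5 ± 5.60 CPM. Gclc was 40 ± 1.00 and 46.7 ± 1.92 CPM (edgeR adjusted p = 0.0256). This rise did not pass with unstranded counts (edgeR adjusted p = 0.0527) or in DESeq2 (adjusted p = 0.0525). It was also lost in edgeR without scramble replicate 2 (adjusted p = 0.0957) or 3 (0.0558), or without knockout replicate 1 (0.0542) or 2 (0.0860). With GC and length offsets and the replicate block, the edgeR adjusted p was 0.0506. Osteoclast differentiation genes fell in 8 of 10 members and rose in 1 (median -1.18; camera adjusted p = 0.000615, and adjusted p = 0.0545 with an estimated correlation). The fusion gene Ocstamp fell from 135 ± 7.31 to 14.4 ± 2.41 CPM and the carbonic anhydrase gene Car2 from 328 ± 5.90 to 157 ± 4.6 CPM, while Nfatc1 rose from 57.3 ± 1.52 to 93.6 ± 3.56 CPM.

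**Figure D3:**
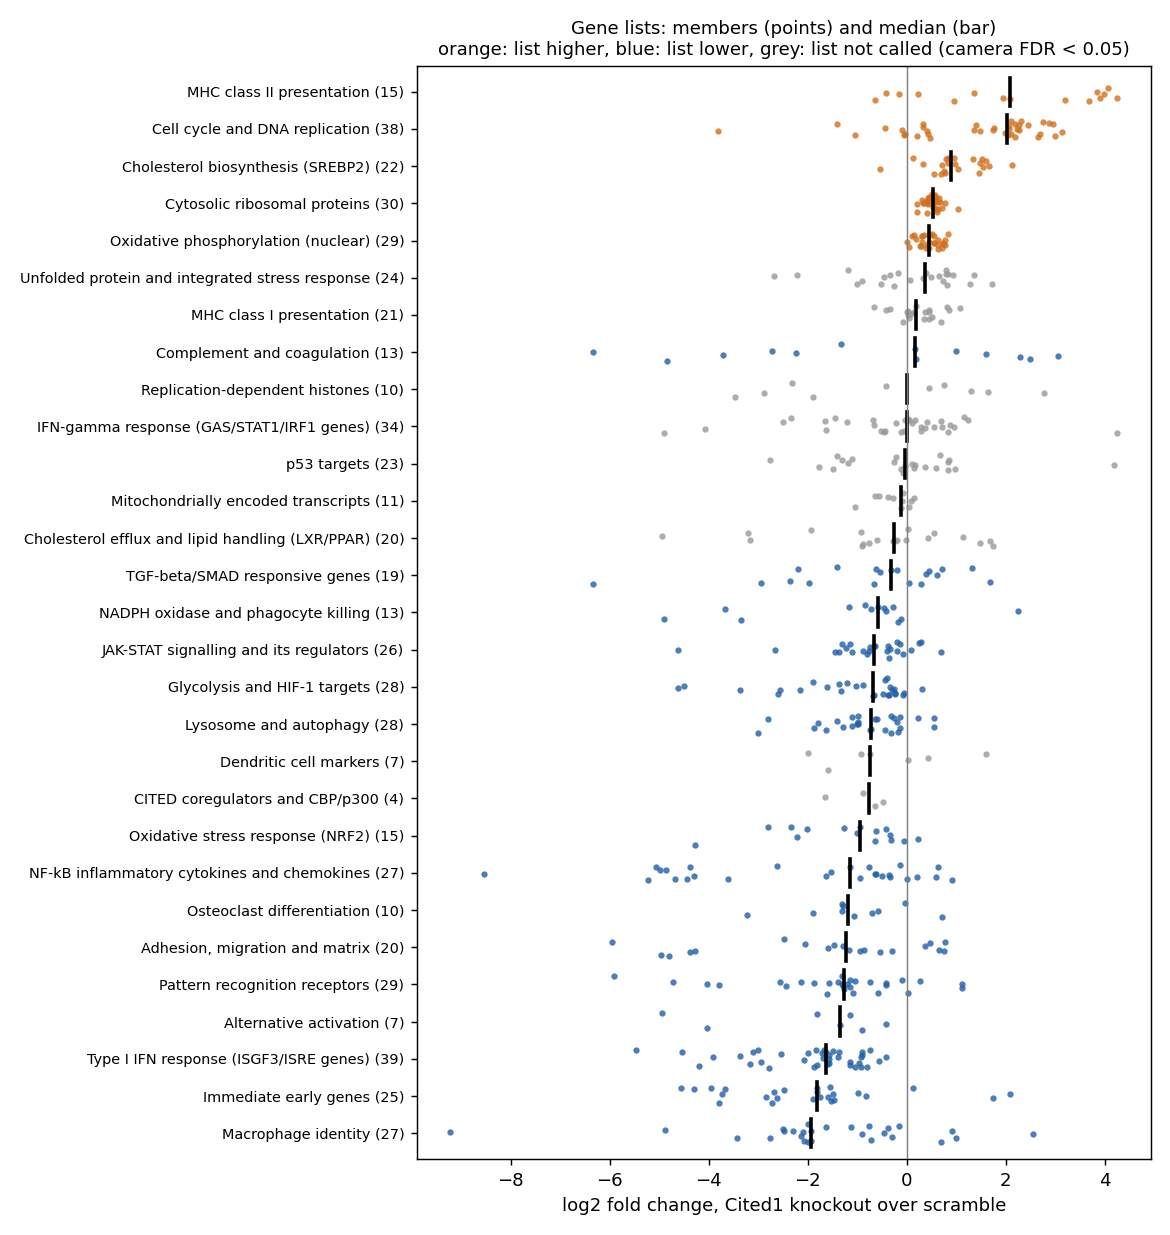
Log2 fold change of Cited1 knockout over scramble (horizontal axis) for the tested members (points) of the 29 lists tested, with the median as a black bar and the number of members in brackets. Lists called higher are orange, lists called lower are blue and lists not called are grey. All 39 type I interferon genes lie below 0.

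Proliferation genes were higher in the knockout. Of 38 cell cycle and DNA replication genes, 30 rose, 25 of them at least 2-fold, and 4 fell (median log2 fold change 2.02; camera adjusted p = 1.88e-23, and adjusted p = 0.0386 with an estimated correlation). Mki67, a marker of cycling cells, rose from 99.4 ± 4.72 to 541 ± 16.1 CPM and the cyclin gene Ccna2 from 29.8 ± 2.14 to 231 ± 16.6 CPM. The inhibitor gene Cdkn1a fell from 1233 ± 92.2 to 466 ± 49.0 CPM and Ccnd2 from 101 ± 3.76 to 48.5 ± 4.34 CPM. The p53 target list was not called, with 9 of 23 members higher and 8 lower (camera adjusted p = 0.69), and its median of -0.032 turned to 0.15 with library size scaling. In that list Eda2r rose from 0.49 ± 0.28 to 9.03 ± 1.79 CPM, Aen rose from 36.6 ± 3.57 to 65.3 ± 6.21 CPM and the death receptor gene Fas fell from 139 ± 2.23 to 64.4 ± 1.68 CPM. In the histone list, which also holds variants with polyadenylated messages such as H2afz, 5 of 10 rose and 4 fell (camera adjusted p = 0.387).

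Metabolic lists moved in different directions. Cholesterol biosynthesis genes rose in 20 of 22 members and fell in 1 (median 0.90; camera adjusted p = 8.47e-08, and adjusted p = 0.0332 with an estimated correlation). Cyp51 rose from 37.4 ± 1.68 to 105 ± 1.52 CPM and Stard4 from 28.7 ± 0.86 to 91.3 ± 6.90 CPM, while the receptor gene Ldlr fell from 169 ± 10.7 to 117 ± 11.8 CPM. In the list of cholesterol efflux and lipid handling, 5 of 20 rose and 12 fell (camera adjusted p = 0.277, not called). There the fatty acid enzyme genes Scd1 (59.9 ± 0.66 to 201 ± 5.99 CPM) and Fasn (94.1 ± 4.13 to 301 ± 33.7 CPM) rose, and Plin2 (318 ± 14.1 to 34.5 ± 3.24 CPM) and the scavenger receptor gene Cd36 (3589 ± 155 to 938 ± 66.2 CPM) fell. Glycolysis and HIF-1 target genes fell in 25 of 28 members and rose in 1 (median -0.68; camera adjusted p = 3.11e-07, and adjusted p = 0.271 with an estimated correlation). The hexokinase gene Hk1 fell from 661 ± 22.5 to 263 ± 6.30 CPM and Adm from 33.4 ± 7.87 to 1.50 ± 0.36 CPM. Pdk1 was 71.8 ± 6.03 and 89.4 ± 16.5 CPM; its libraries overlapped, and its call (edgeR adjusted p = 0.0248) was lost when scramble replicate 1 (adjusted p = 0.104), scramble replicate 2 (0.0952) or knockout replicate 1 (0.0834) was left out.

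Nuclear genes of oxidative phosphorylation rose in 25 of 29 members and fell in 0 (median 0.46; camera adjusted p = 0.000427, and adjusted p = 0.342 with an estimated correlation). Atp5a1 rose from 591 ± 24.7 to 1010 ± 21.3 CPM and Cyc1 from 90 ± 3.06 to 149 ± 3.25 CPM. Of 11 mitochondrially encoded transcripts, 3 fell and 0 rose (camera adjusted p = 0.594), with a median of -0.11 that turned to 0.071 with library size scaling; mt-Cytb fell from 214 ± 36.8 to 104 ± 9.43 CPM. All 30 cytosolic ribosomal protein genes rose (median 0.54; camera adjusted p = 1.11e-05, and adjusted p = 0.442 with an estimated correlation), Rpl3 from 711 ± 31.4 to 1460 ± 64.6 CPM. The unfolded protein and integrated stress response list had 13 of 24 members higher and 9 lower (camera adjusted p = 0.262). In it the serine and one-carbon enzyme genes Phgdh (181 ± 10.2 to 465 ± 18.7 CPM) and Shmt2 (129 ± 8.30 to 425 ± 11.9 CPM) rose, and Slc7a11 (93.5 ± 3.43 to 19.8 ± 3.43 CPM) fell.

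Genes of adhesion, migration and matrix fell in 15 of 20 members and rose in 4 (median -1.23; camera adjusted p = 1.87e-08, and adjusted p = 0.0400 with an estimated correlation). Among the integrin genes, Itga6 fell from 93.2 ± 13.2 to 2.98 ± 0.30 CPM and Itga5 from 454 ± 11.8 to 109 ± 8.14 CPM, while Itga4 rose from 157 ± 9.35 to 265 ± 7.76 CPM and Itgal from 290 ± 17.3 to 458 ± 20.3 CPM. TGF-β responsive genes fell in 11 of 19 members and rose in 5, or 11 and 6 adjusted over the list alone (median -0.31; camera adjusted p = 0.0102, and adjusted p = 0.0890 with an estimated correlation); the call was also lost in limma-voom (camera adjusted p = 0.130). Serpine1, the plasminogen activator inhibitor gene (chromosome 5, 137061504 to 137072268), fell from 2243 ± 226 to 27.9 ± 3.63 CPM, while Smad3 rose from 3.56 ± 0.47 to 11.6 ± 3.10 CPM. In the complement and coagulation list, 5 of 13 rose and 6 fell. Its median of 0.16 has no stable sign (-0.14 without knockout replicate 1, -1.32 without the low-count filter and -0.58 in genes without a gene on the other strand). Its mean was -0.80 and camera called it lower (adjusted p = 0.000680), a call lost in limma-voom (adjusted p = 0.446) and with an adjusted p = 0.107 with an estimated correlation. C1qb rose from 70.2 ± 8.81 to 213 ± 20.5 CPM and C1qc from 40.1 ± 1.73 to 195 ± 22.9 CPM, whereas the receptor genes C3ar1 (222 ± 17.7 to 7.74 ± 1.66 CPM) and C5ar1 (97.8 ± 4.24 to 7.52 ± 0.75 CPM) fell.

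Markers of other cell types were counted at low levels, with exceptions. Of 7 tested dendritic cell markers, 2 rose and 4 fell (camera adjusted p = 0.271); all 7 were at 1 CPM or more in scramble, and 2 belong to another list. Itgax fell from 115 ± 3.16 to 38.3 ± 1.12 CPM, and Clec9a rose from 130 ± 2.03 to 175 ± 9.06 CPM. The lymphocyte, neutrophil and mast cell, and fibroblast and epithelial lists had 2 tested members each, too few for camera. The immunoglobulin gene Ighm rose from 21.7 ± 4.17 to 84.9 ± 4.6 CPM. The mast cell factor gene Gata2 fell from 1.63 ± 0.74 CPM to 0 counts, at least 19.7-fold lower, and Acta2 fell from 3.22 ± 1.24 to 0.78 ± 0.22 CPM.

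No chromosome was shifted as a whole. With the tested genes of each of 20 chromosomes as a set, 0 were called by camera on the edgeR fit, at an adjusted or at an unadjusted p of 0.05. With an estimated correlation 1 had an unadjusted p below 0.05, and its adjusted p was 0.429. Chromosome medians of the log2 fold change lay between -0.086 and 0.096. DESeq2 and limma-voom also called 0 chromosomes.

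The calls were set beside the authors' deposited table, which lists 7690 transcript rows of 6430 genes, 3799 of them up and 3891 down in the knockout. Of 5213 genes with 1 row that were tested here, 4968 were also called here, and 4967 of those (99.98%) had the same direction. Log2 fold changes correlated across genes at r = 0.975 (genes are not independent replicates). Of the 9061 genes called here, 5967 (65.9%) are in that table. It was made from the same libraries, so the overlap is not independent evidence.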

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

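Several kinds of reads that did not enter the gene counts differed between the groups, with no overlap between their libraries. Unmapped reads were 4.77% ± 0.08 (SD, n = 3) of the reads in the knockout and 3.41% ± 0.10 (SD, n = 3) in scramble, and the lowest knockout library (4.69%) lay above the highest scramble library (3.48%). Multiply mapped reads were 5.63% ± 0.10 (SD, n = 3) in the knockout and 4.63% ± 0.05 (SD, n = 3) in scramble, again with no overlap. Reads with no gene on the reverse strand, the largest kind, differed the other way, 45.5% ± 0.35 (SD, n = 3) in the knockout and 46.8% ± 0.26 (SD, n = 3) in scramble, while without regard to strand reads with no gene overlapped between the groups (3.79% to 5.39% and 4.27% to 4.94%). Most reads with no gene on the reverse strand thus lie in genes when strand is ignored. What the unmapped and multiply mapped reads come from was not tested, and all these reads were left out of the comparisons on the reverse column. Groups of 3 libraries are too small for the check of single libraries far from their group, and there is 1 contrast only, so no effect could be compared between groups of samples.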

How the results depend on the processing

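The tests with GC content and length offsets and the one without overlapping genes were chosen after the results were seen. The count of 9061 changed genes lay between 8491 and 9397 in all other settings, leaving out each library included (8491 to 9019), and was 8677 in DESeq2, 9101 in limma-voom and 9127 with GC and length offsets. Restricted to genes without a gene on the other strand, 5944 genes changed, 2964 higher and 2980 lower, because only 8383 genes were tested; 5941 of them had been called in the same direction. For lists, an estimated inter-gene correlation left 9 of 20 calls, 3 higher and 6 lower, and fry, which asks whether a list moves on balance and does not compare it with other genes, gave 8 higher; the cause was not tested. Cited1 and the 0 shifted chromosomes kept their direction and side of the threshold in all settings run. The overlap with the authors' table was computed only for the fit used for the tests. There 99.98% of the shared calls, and 100% of those at least 2-fold, had the same direction. No named gene reversed; Ptpn2, Pdk1 and Gclc lost their call in some settings, 12 times in all.

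The replicate numbers did not pair the libraries: the deviations of libraries with the same number correlated at -0.055, -0.00065 and -0.072 across genes, none above 0.1. With the replicate number as a block, 8749 genes changed, of which 8731 were shared with the unblocked fit, and 8814 with GC and length offsets as well. Scramble replicate 1 correlated best with knockout replicate 3, not with its own number. Depth limits genes of few CPM, such as Cited1. A library holds 13 to 53 counts of it on the reverse column, and 25 to 123 without regard to strand.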

Other observations

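The gene families in this paragraph were chosen after the values were seen, hold protein-coding genes only, and were tested with camera on the same fit. Further families were tested and are not given, and the adjustment was over all of them. Some members, such as Slfn1, Clec4e and Ccl9, are also in the lists above, so these tests add no separate evidence. All 12 tested members of the IFI200 family of DNA-sensing and interferon-inducible proteins fell (median log2 fold change -1.85; camera adjusted p = 9.62e-17, and adjusted p = 0.0608 with an estimated correlation). Of 7 Schlafen genes, 6 fell and 1 rose (median -2.43; camera adjusted p = 8.81e-09, and adjusted p = 0.0484 with an estimated correlation); both families are clusters of similar genes, so their counts can be split between copies. C-type lectin receptor genes fell in 9 of 13 members and rose in 4 (adjusted p = 0.000685, and 0.0834 with an estimated correlation), chemokine genes fell in 10 of 15 and rose in 2 (4.61e-07, and 0.0341), and Fc receptor genes fell in 5 of 6 (7.23e-07, and 0.0341). Centromere protein genes rose in 17 of 20 and fell in 2 (median 1.76; adjusted p = 6.96e-07, and 0.0341 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 51 of 77 and fell in 3 (adjusted p = 0.000601, and 0.247 with an estimated correlation), and aminoacyl-tRNA synthetase genes rose in 13 of 20 and fell in 0 (0.00536, and 0.332). Proteasome subunit genes were not called, with 13 of 39 higher and 12 lower (adjusted p = 0.765).

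In the patterns below, the tests of scaling, chromosomes, deletions of genes that do not overlap, the X chromosome, a general weakening and mixed-in B, T or dendritic cells were chosen after the result was seen.

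The first pattern is the breadth of the difference, 9061 of 13112 genes. Scaling by library size alone left 89.5% of the calls in their direction. It differs from the scaling used here by a median of only 0.18 in log2, so most calls depend little on the choice between them. Both scalings are relative, so they cannot test a difference in total RNA per cell. The chromosome accounted for 0.428% of the variance of log2 fold changes, which argues against whole-chromosome copy number as the whole cause. Of the 10 splits of the 6 libraries, 1, the real one, gave as many genes. The highest other split gave 0 by edgeR (20 to 85 at an unadjusted p of 0.05) and 0 by DESeq2 and limma-voom. Every other split mixes the 2 groups, so their difference becomes spread within a group and few calls can follow. The splits therefore decide nothing, and 10 splits are also too few for a share under 0.05. Because 1 knockout clone was sequenced, loss of CITED1 and other differences between this clone and the scramble cells cannot be told apart, and a second clone would be needed.

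The second pattern is 30 genes at 10 CPM or more in scramble and under 0.5 CPM in the knockout, against 6 genes the other way, of which Mmp11 and Chchd10 overlap each other on opposite strands and share reads. Of adjacent tested genes, 2 pairs were absent together (95th percentile of 10000 random placements, 1), but both pairs, Rgs16 with Gm28513 and Maf with Gm15655, overlap on opposite strands and share reads, so these pairs do not decide; no pair that does not overlap, 0, was absent together. Both nearest neighbours that do not overlap the gene kept over 25% of their scramble level for 21 of the 30 genes (70.0%), fewer than for all tested genes (90.6%; 5th percentile of random sets of 30 genes, 24), so deletion or silencing across several genes is not excluded. Of the 30, 5 (16.7%) lie on the X chromosome, Maged1, Slc9a7, Arhgap6, Tlr8 and Syn1, against 2.78% of the other tested genes. The odds ratio was 7.0 (95% interval 2.08 to 18.8, Fisher's exact p = 0.00136). Arhgap6, Tlr8 and Syn1 were chosen after their values were seen. Slc9a7 (20105754 to 20291807) lies near Syn1 (20860511 to 20921004), and Tlr8 (167242696 to 167264329) near Arhgap6 (168795099 to 169304435). Fisher's test counts each gene as independent, so this interval and p may be too narrow and too small. A candidate explanation for the genes on X is that RAW 264.7 cells, which derive from a male mouse, carry a single X copy. Then 1 silencing or loss event in a clone may remove a gene's transcript. An effect of CITED1 stays open as well.

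The third pattern is that all 39 type I interferon genes fell while 12 of 15 MHC class II genes rose. A general weakening of IFNγ responses would lower the IFNγ list too. Of its 34 members, 14 (41.2%) were higher, or 13 of 33 without Ciita, which is also in the class II list. Another 14 were lower, 8 of them at least 2-fold against 3 higher. Among all 13112 tested genes, 4529 were higher and 4532 lower, so the share of higher members is near that of all genes. The list did not fall as the type I list did, but a weakening of these responses is not excluded. The labels also do not say whether IFNγ was given. B or T cells mixed into the knockout libraries would bring their own abundant transcripts, yet 18 lymphocyte markers other than Ighm summed to 0.122% of the CPM of Cd74, with Cd19, Cd79a, Cd79b and Ms4a1 at 0 counts there (Cd74 and the 7 markers below were chosen after the list values, which hold Cd74 and some of the markers, were seen). With Ighm, which rose from 21.7 to 84.9 CPM, the whole list of 19 genes went from 28.8 to 91.0 CPM. Cd74 was at 4968 CPM in the knockout. The small sum thus holds only without Ighm. Dendritic cells are not settled: 7 of their markers summed to 0.213% of Cd74 in the knockout, but the whole list of 14 genes, which went from 697 to 524 CPM, summed to 10.6% of it; of the 7, Zbtb46 rose from 1.85 ± 1.01 to 5.79 ± 1.17 CPM and Xcr1 fell from 7.85 ± 0.62 to 4.09 ± 1.54 CPM, Ccr7, Flt3, Batf3 and Cd209a went from 0, 0, 7 and 0 counts to 9, 3, 13 and 1, and Siglech had 0. Less autocrine type I interferon in the knockout is a candidate explanation that cannot be settled here, since Ifnb1 had only 30 reads over all 6 libraries, 22 in scramble and 8 in the knockout, and was not tested, and an effect of CITED1 and a difference in the state of the clone, such as a higher share of cycling cells, also remain open.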
